A study of Mus musculus with 6 samples.

How the data were processed

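Gene expression was measured in neurons sorted by flow cytometry from the brains of E14.5 mouse embryos, using a green fluorescent protein (GFP) allele at the Pitx3 locus as the marker. The 6 two-colour arrays compared 3 pools of Pitx3(gfp/+) neurons, called heterozygous here, with 1 shared pool of Pitx3(gfp/-) neurons, called null here. Each heterozygous pool was hybridised against the null pool on 2 arrays with the dyes swapped. Each pool held several embryos, and the RNA went through 2 rounds of T7 amplification, per the labels' protocols. The brain region that was dissected is not described further in the sources used here.

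Per the file headers, the scanner tables hold the intensity of each spot and of its local background for the 2 channels, with no normalization. The first channel tracked the deposited Cy5 values and the second the Cy3 values on every array, which settled the dyes together with the labels. The authors also deposited normalized intensity values for each dye, from which no background had been subtracted, as the values show. The authors' series table holds log2 values that equalled the log2 of the normalized Cy5 over Cy3 signal at every spot, with array medians between -0.00058 and 0.0023 and without a change of sign for the swapped arrays. How the authors normalized their values is not given in the sources used here.

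The scanner intensities were the starting point. Of 45220 spots, 4046 were control spots, and 41174 held probes. Of those probes, 34186 had 1 gene symbol in the platform annotation, 0 had several and 6988 had none. Symbols were updated with a RefSeq gene table of assembly GRCm38.p6: 30365 probes carried a symbol of that table, 3726 were updated through an older name and 95 kept the name as given. From that table, genomic span was also used in checks of short against long genes; no coordinates are reported. The probes represented 18295 genes, 8946 of them with several probes.

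Background was corrected with limma's normexp method and an offset of 50, which shrinks the ratios of dim probes toward 0. Each array was normalized by loess with control spots at weight 0, and every log2 ratio was turned to read null over heterozygous. The 2 arrays of a pool were averaged, so that n = 3 pools. A gene was represented by its probe with the highest mean intensity. The log2 ratio was tested against 0 with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. This test measures the spread of the 3 heterozygous pools and leaves out the spread of null pools, since there was 1. A probe counted as well above background on an array when its signal exceeded the local background median by more than 2 background SDs. A gene counted as above background when this held on at least 3 of the 6 arrays in either RNA. Precision is limited by the number of arrays and pools.

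Gene lists for dopaminergic neurons, other cell types and general cell functions, 29 in all, were tested with camera at a preset correlation of 0.01. The ribosomal protein and oxidative phosphorylation lists were taken by the start of the symbol, so they also hold related genes such as Rps19bp1 and assembly factors such as Ndufaf1. Camera with an estimated correlation and fry were the alternatives, and Benjamini-Hochberg adjustment ran over the 29 lists. The named genes followed a rule: Pitx3, every measured gene of the dopamine handling list, the 12 largest rises and 12 largest falls among genes past the threshold with a proper symbol and the same sign on all 6 arrays, and for each list up to 4 members past the threshold with the largest log2 ratios in size. The rule named 74 genes. Genes outside it are said to be so or to be chosen after their values were seen. The lists, this rule, the tests and most alternatives were chosen before the data were examined.

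The alternatives covered background correction, normalization, the authors' values, a filter on dim probes, the mean over probes, the treatment of the paired arrays, each dye orientation alone, other variance models and leaving out each pool. The fit was tested on simulated data of 18295 genes in 3 pools, with 200 genes changed. It recovered 90% of the genes changed by 0.5 and 99% of those changed by 1 on the log2 scale, with 17 false calls among 206. In that simulation the null RNA had no variation of its own. The changed genes were drawn from the brighter genes, and the changes were added to the final log2 ratios. Recovery of dim genes, whose ratios the offset shrinks, was therefore not tested.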

Results

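Expression profiles of sorted Pitx3-GFP neurons were compared between Pitx3 null and heterozygous E14.5 mouse embryos. Pitx3 is a homeodomain transcription factor of midbrain dopaminergic neurons. The series title places the comparison in a study of dopaminergic subsets and of neuronal vulnerability in Parkinson's disease. The data comprised 6 arrays, with 3 heterozygous pools each measured against the same null pool in both dye orientations. Between 47.6% and 71.4% of the 18295 genes were well above background in a given RNA on a given array, and 12291 genes were above background by the criterion of at least 3 arrays. Log2 ratios correlated across genes at 0.61 to 0.72 between the swapped arrays of a pool, at 0.53 to 0.63 between arrays of different pools with the same dyes, and at 0.37 to 0.50 between arrays of different pools with swapped dyes. Genes are not independent replicates in these correlations.

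The targeted gene was examined first. Pitx3 gave a log2 ratio of -0.08 ± 0.32 (SD, n = 3 pools), with an adjusted p of 0.811. The pools read -0.45, 0.12 and 0.07, and the mean was 0.10 without replicate 1, 0.14 on the arrays with the null RNA in Cy5 and -0.31 on those with it in Cy3. The probe was well above background on all 6 arrays in both RNAs. Both genotypes carry the GFP allele at this locus, and the position of the probe in the gene is not known here, so the value checks nothing about the labels.

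Among the 18295 genes, 566 were higher and 342 lower in the null pool, 908 in all at an adjusted p under 0.05. The largest rises were in Atp5e, the epsilon subunit of ATP synthase, at 1.34 ± 0.35 (log2, SD, n = 3), and in the peroxisomal membrane protein gene Pex11g at 1.29 ± 0.31. The 2 histone H2A genes H2ac23 and H2ac10 rose by 1.15 ± 0.26 and 1.09 ± 0.34. Ifitm3, an interferon-induced membrane protein gene, rose by 1.14 ± 0.32, and P2rx2, an ATP-gated ion channel gene, by 1.02 ± 0.21. The largest falls were in the RNA-binding protein gene Celf4, which was 1.99-fold lower in the null pool (SD of its log2 ratio 0.28), and in Ccar1, a regulator of cell division and apoptosis, at -0.98 ± 0.15. Mapt, which encodes the microtubule-associated protein tau, fell by 0.84 ± 0.18.

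The other large rises were in Slc16a12, Ndufa4, Rps20, Rbbp4, Rps14 and Rplp2, with log2 ratios from 0.97 to 1.12. Rbbp4, a histone-binding protein gene, had the narrowest spread of these, at 1.00 ± 0.042. The other large falls were in Rsrp1, Nr4a1, Fos, Hnrnpa2b1, Pogz, Golga4, Cdon, Msmo1 and Egr4, with log2 ratios from -0.89 to -0.74. Cdon encodes a co-receptor of sonic hedgehog, Hnrnpa2b1 a splicing factor and Msmo1 an enzyme of sterol synthesis. Most changes were small: the median size among the 908 genes was 0.36, 9 genes rose at least 2-fold and 0 fell that far. All 6 arrays gave the same sign for 893 of the 908 genes. This follows largely from the selection, since a call needs a small spread over pools and all arrays share the null pool. Among 428 further probes of called genes that were above background, 282 had the sign of the brightest probe, and 100 of these had an unadjusted p under 0.05. The remaining further probes did not have that sign. Each value given for a gene is that of its brightest probe alone.

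**Figure D1:**
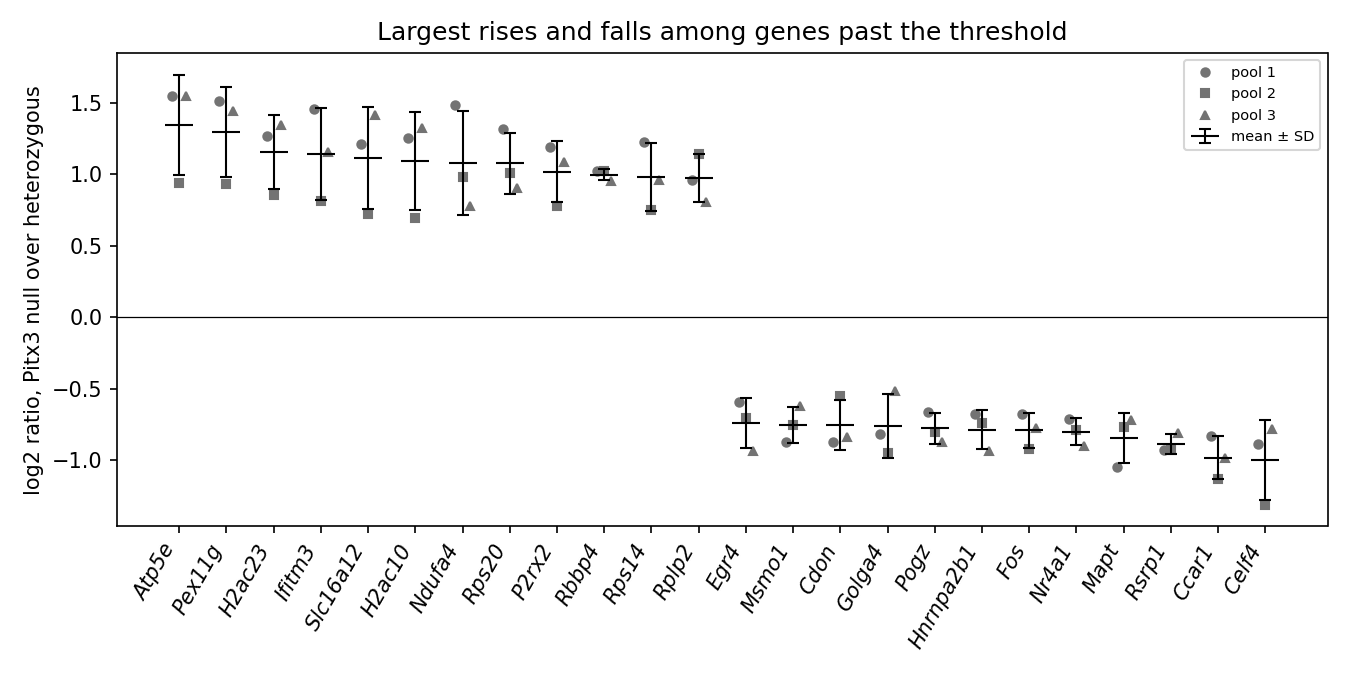
Log2 ratio, null over heterozygous, of the 12 largest rises and 12 largest falls past the threshold. Points are the 3 heterozygous pools (each the mean of 2 dye-swapped arrays), and bars the mean ± SD; the means of the rises reach 1.34, for Atp5e and Celf4 is 1.99-fold lower. The naming rule admits only genes with 1 sign on all 6 arrays.

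The smallest adjusted p was 0.0260, close to the threshold, and the calls ended in several settings. With limma, 0 genes passed when any 1 pool was left out (2956 to 3259 genes at an unadjusted p under 0.05), with plain background subtraction (3454), with median centring in place of loess (2604) or with a trended robust variance (3069), and 0 with a one-sample test without moderation (2573), against 3753 here.

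Of the dopamine handling genes, 2 passed the test over all genes. Slc6a3, the dopamine transporter, fell by 0.42 ± 0.018 (log2, SD, n = 3 pools; adjusted p = 0.0260). Its probe was well above background on 6 arrays in the heterozygous RNA but on 2 of 6 in the null RNA, with a mean null signal of 55.3 over a background of 43.3. The size and spread of its ratio are therefore shaped by the background and the offset. Pts, an enzyme of tetrahydrobiopterin synthesis, fell by 0.23 ± 0.045 (adjusted p = 0.0392). Th and Gch1, which encode tyrosine hydroxylase and the first enzyme of tetrahydrobiopterin synthesis, were not well above background in either RNA on any array, so no ratio is given. The other 9 measured members did not pass: Ddc read 0.02 ± 0.032, Slc18a2 0.01 ± 0.052, Drd2 -0.04 ± 0.045, Dbh 0.04 ± 0.025, Qdpr -0.04 ± 0.050, Maoa -0.19 ± 0.32, Maob -0.16 ± 0.21, Pcbd1 0.15 ± 0.049 and Spr 0.14 ± 0.065. Ddc, Dbh and Slc18a2 were dim, with mean signals of 61.9 to 69.4 over backgrounds of 39.9 to 42.0. The offset shrinks such ratios toward 0, so their small values and SDs do not show unchanged levels. Of 13 members, 0 rose and 2 fell, and adjusted over the list alone 2 rose and 2 fell. The list as a whole did not pass, with a median of -0.04 (camera adjusted p = 0.487). It did not pass in fry either, though its fry adjusted p of 0.0619 was the lowest of the 29 lists.

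**Figure D2:**
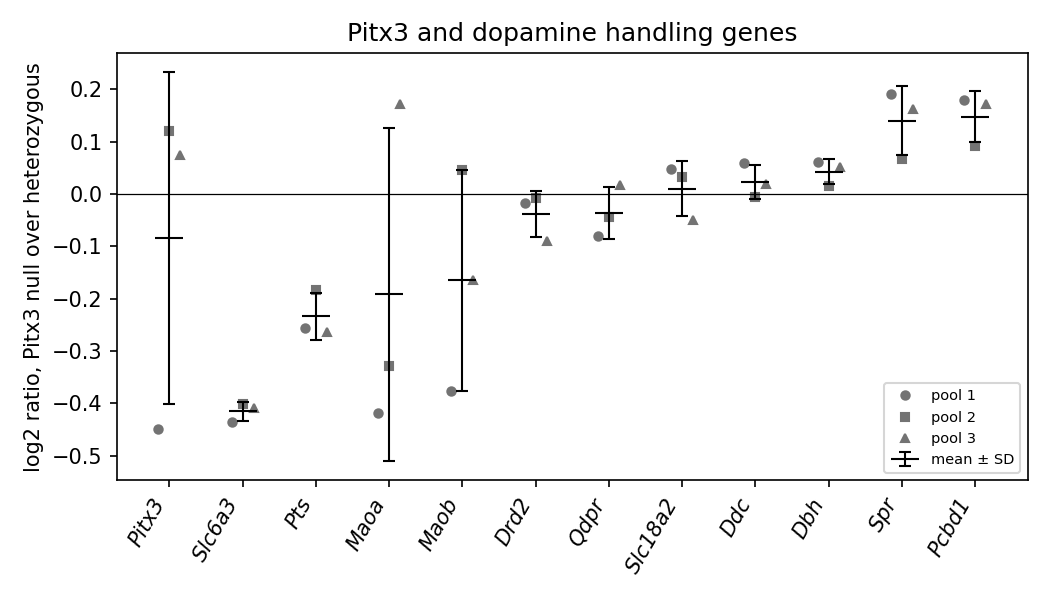
Log2 ratio, null over heterozygous, of Pitx3 and of the 11 dopamine handling genes with signal above background on any array. Points are the 3 heterozygous pools and bars the mean ± SD; Slc6a3 lies at -0.42 with an SD of 0.018, while the 3 pools of Pitx3 run from -0.45 to 0.12.

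Other lists of the dopaminergic lineage held single calls or none. Among 23 transcription factors of midbrain dopaminergic neurons, 0 rose and 1 fell, the early B-cell factor gene Ebf3 at -0.56 ± 0.12. Adjusted over the list alone, 0 rose and 2 fell. Uncalled members, chosen here after their values were seen, included Nfib at -0.41 ± 0.39, En2 at -0.35 ± 0.24, Nr4a2 at -0.31 ± 0.25 and Foxa2 at -0.27 ± 0.099 (adjusted p = 0.0633). The highest was Msx1 at 0.13 ± 0.074; En1 and Ebf1, also above 0, were not well above background on any array. This list passed camera with the dim-probe filter and without replicate 3, both with the preset correlation. With an estimated correlation on all genes and pools its p was 0.259 (adjusted p = 0.695). Of 14 genes associated with the rostrolateral part of the dopaminergic field or the substantia nigra, 0 rose and 1 fell (the same adjusted over the list alone), the transporter gene Slc10a4 at -0.31 ± 0.078. Among 16 genes of the caudomedial or ventral tegmental part, 0 rose and 0 fell by either adjustment. In the 14 earlier target genes of Nr4a2 and Pitx3, Slc6a3 was the 1 call; adjusted over the list alone, 3 rose and 1 fell. Retinoic acid pathway genes (20) and neurotrophic factors and receptors (21) had 0 calls by either adjustment. Camera adjusted p-values of these lists were 0.133, 0.795, 0.355, 0.985, 0.451 and 0.795 in the order given.

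The lists of ribosomal protein and oxidative phosphorylation genes passed camera with the preset correlation, toward higher levels in the null pool. In camera with an estimated correlation neither list passed (p = 0.0829 and p = 0.0583, adjusted p = 0.695 for both). A list could hardly pass there, since that form takes its degrees of freedom from the 3 pools. Neither list passed in fry, which tests whether a list moves one way (adjusted p = 0.0832 for both). Of 59 ribosomal protein genes, 23 rose, 0 fell and 36 did not pass, and 41 rose and 0 fell adjusted over the list alone. Rps20 was at 1.08 ± 0.21, Rps14 at 0.98 ± 0.24, Rplp2 at 0.97 ± 0.17 and Rpl37a at 0.89 ± 0.17. Of 92 oxidative phosphorylation genes, 46 rose, 0 fell and 46 did not pass, and 63 rose and 2 fell adjusted over the list alone. Besides Atp5e, these included Ndufa4 at 1.08 ± 0.36, Cox7a2 at 0.93 ± 0.17 and Uqcrq at 0.86 ± 0.036, which encode parts of the respiratory chain. The list medians were 0.34 ± 0.11 and 0.33 ± 0.045 (SD of the 3 pools' medians), against a median of -0.0027 over all genes. With the dim-probe filter the ribosomal protein median was 0.59. Ratios above 0 were found for 53 of 59 and 82 of 92 members. Outside both lists, short genes read higher than long ones in the null pool (Spearman's rho of -0.25 between log2 ratio and genomic span across 12127 genes above background, which are not independent replicates). Camera with the preset correlation, which lies far below the estimated ones, gave adjusted p-values of 4.75e-20 and 1.65e-26. These were the 2 lists of 29 that passed with the preset correlation.

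**Figure D3:**
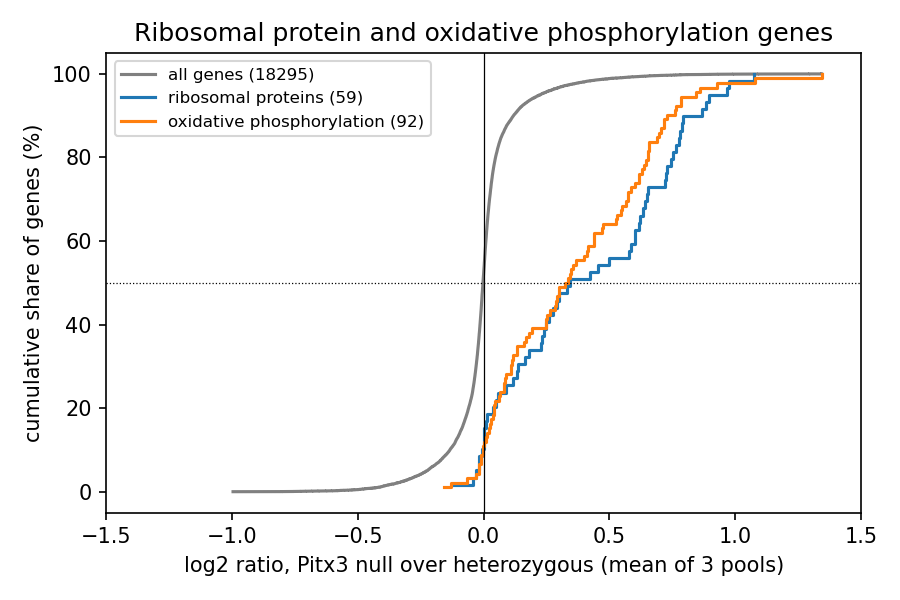
Cumulative share of genes (%) by log2 ratio, null over heterozygous, for all 18295 genes and for the 59 ribosomal protein and 92 oxidative phosphorylation genes. The curves of both lists lie to the right of that of all genes, with medians of 0.34 and 0.33 against -0.0027.

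Neuronal genes moved in both directions. Of 28 pan-neuronal genes, 2 rose and 5 fell by either adjustment, among them Celf4, Mapt and the secretory granule gene Chgb (-0.57 ± 0.17), while the synapsin gene Syn1 rose by 0.56 ± 0.13. Among 16 Parkinson disease genes, 1 rose and 2 fell: Park7 rose by 0.22 ± 0.022, and Mapt and the synaptojanin gene Synj1 (-0.38 ± 0.072) fell. Adjusted over the list alone, 2 rose and 2 fell. Axon guidance genes had 3 falls among 42, in the receptor genes Plxna2 (-0.43 ± 0.075) and Epha7 (-0.34 ± 0.096) and in Sema6d (-0.21 ± 0.023), with 0 rises. Adjusted over the list alone, 4 rose and 7 fell. Of 29 channels and receptors, Cacna2d2 rose by 0.34 ± 0.077 and the glutamate receptor gene Gria1 fell by 0.33 ± 0.093; adjusted over the list alone, 2 rose and 1 fell. Of 22 neuropeptides, Tac2 rose by 0.30 ± 0.011 and the enkephalin gene Penk fell by 0.43 ± 0.13, with 2 rises and 2 falls adjusted over the list alone. Camera adjusted p-values were 0.153, 0.795, 0.226, 0.901 and 0.439.

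Among the lists of other neurons, the GABAergic list had 1 rise and 3 falls among 18 genes (1 and 5 adjusted over the list alone): Sox14 at 0.22 ± 0.032, and the transcription factor genes Gata3 at -0.33 ± 0.080, Tal1 at -0.29 ± 0.060 and Lhx5 at -0.24 ± 0.067. Gata3 was also the 1 fall among 13 serotonergic genes, with 0 rises, by either adjustment. Pou4f1, a factor of red nucleus neurons, rose by 0.44 ± 0.064 as the 1 call among 19 glutamatergic, red nucleus and diencephalic genes, by either adjustment. The 14 cholinergic and oculomotor genes had 0 calls by either adjustment. Camera adjusted p-values were 0.226, 0.959, 0.226 and 0.330.

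Among the lists of progenitors and non-neuronal cells, Id1, a helix-loop-helix inhibitor of differentiation, rose by 0.50 ± 0.054 as the 1 call among 33 radial glia and floor plate genes, by either adjustment. Among 35 cell cycle genes 3 rose and 0 fell by either adjustment: Cks2 at 0.75 ± 0.089, Cdc20 at 0.32 ± 0.081 and Birc5 at 0.22 ± 0.042. The embryonic globin gene Hbb-y rose by 0.37 ± 0.060, with 1 rise among 11 erythroid genes and 3 adjusted over the list alone. The endothelial genes Cd34 (-0.41 ± 0.13) and Sox17 (-0.37 ± 0.12) were 2 falls among 19, with 0 rises, by either adjustment. Postn rose by 0.24 ± 0.031, the 1 call among 21 mesenchyme and pericyte genes by either adjustment. The glutamate transporter gene Slc1a2 fell by 0.41 ± 0.11 as the 1 call among 18 genes of the oligodendrocyte and astrocyte lineage; adjusted over the list alone, 1 rose and 1 fell. The 18 genes of microglia and macrophages had 0 calls by either adjustment. Camera adjusted p-values were 0.108, 0.483, 0.194, 0.483, 0.901, 0.795 and 0.451.

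Of 26 immediate early and dissociation response genes, 2 rose and 5 fell, and 2 rose and 7 fell adjusted over the list alone. Nr4a1 fell by 0.80 ± 0.092, Fos by 0.79 ± 0.12 and Jun by 0.51 ± 0.15, all transcription factor genes induced within minutes of a stimulus. Klf2 rose by 0.53 ± 0.16. The camera adjusted p was 0.0575, and with an estimated correlation p = 0.171. Among 22 apoptosis and p53 genes, Trp53inp1 fell by 0.36 ± 0.085 as the 1 call by either adjustment (camera adjusted p = 0.795). Cholesterol synthesis genes had 1 rise and 2 falls among 18 (1 and 3 adjusted over the list alone): Idi1 fell by 0.65 ± 0.16 and Sc5d by 0.43 ± 0.044, and Ebp rose by 0.27 ± 0.059 (camera adjusted p = 0.154). This list did not hold Msmo1, the sterol synthesis gene among the largest falls. The 4 sex-linked genes had 0 calls by either adjustment (camera adjusted p = 0.901).

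The null RNA was 1 pool, used on all 6 arrays, so the p-values leave out how null pools vary. Taking a heterozygous pool as the shared reference against the other 2 gave 1442 (pool 1), 847 (pool 2) and 726 (pool 3) genes at an unadjusted p under 0.01, and the null pool against the same pairs gave 1343, 1258 and 1246. At an unadjusted p under 0.05 these counts were 3950, 2691 and 2647, against 3259, 2956 and 3234. Heterozygous pools were compared with each other through the null pool. Noise of the arrays of a heterozygous reference therefore enters both of its ratios and tends to raise its counts, unlike those of the null pool.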

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

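Across the 6 arrays, 5 of 76 measures (the 74 named genes and the share of genes above background in each RNA) had 1 array far from the other 5 by Dixon's ratio. Chance flags about 5% of such measures, and the arrays come in dye-swapped pairs of 3 pools. Rbbp4 read 0.89 on the array of pool 3 with the null RNA in Cy3, against 1.00 to 1.05 on the others. On the same array, Nr4a1 read -0.99 against -0.80 to -0.70, and Hnrnpa2b1 read -1.27 against -0.81 to -0.56. Rplp2 read 1.58 on the array of pool 2 with the null RNA in Cy5, against 0.66 to 0.96. Cdon read -0.32 on the array of pool 2 with the null RNA in Cy3, against -0.94 to -0.73.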

How the results depend on the processing

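The 2 alternatives that leave out both general lists or remove the span trend were chosen after the data were seen. The count of 908 genes stayed between 674 and 1070 without background correction, with the authors' values, with the dim-probe filter, with the mean over probes, in each dye orientation and in those 2 added settings; between 530 and 865 of these genes were among the 908. Aquantile scaling cannot move ratios within an array, and gave the same 908. With the 6 arrays in 1 model and a dye term the count was 2221 with pool as a random block and 2891 with the arrays taken as independent, which counts paired arrays as more samples. The counts of all calls and of calls at least 2-fold were both 0 with plain background subtraction, median centring, the trended robust variance and the test without moderation, and both 0 to 0 when leaving out each pool, which leaves 2. The cause was not tested for the first 4. The 2-fold count of 9 was 23 on the arrays with the null RNA in Cy5 and 14 on those with it in Cy3, and 6 to 13 in the other settings with calls. Pitx3 moved from -0.08 to 0.14 with the null RNA in Cy5 and to -0.31 with it in Cy3, and ran from -0.19 to 0.10 when leaving out each pool, and never passed. The ribosomal protein median of 0.34 and the oxidative phosphorylation median of 0.33 lost their call with an estimated correlation and in fry, where the medians are unchanged. The estimated correlations of 0.21 and 0.15 exceed the preset 0.01, which widens the error of a list in camera. That setting also takes its degrees of freedom from the 3 pools in place of the genes, so that any list can hardly pass. The loss in camera therefore does not follow from the wider error alone. The cause in fry was not tested. Both lists passed in the other 8 settings, with the ribosomal protein median at 0.59 in the dim-probe filter, which leaves fewer members. The dopamine handling list passed in none. Another 4 lists passed in some settings: radial glia and floor plate progenitors (median centring, without replicate 1), midbrain dopaminergic transcription factors (dim-probe filter, without replicate 3), immediate early genes (null RNA in Cy5, without replicate 1) and pan-neuronal genes (without replicate 3), all with the preset correlation; with an estimated correlation on all genes and pools, 0 of 29 lists passed (p = 0.195, 0.259, 0.171 and 0.330 for these 4). No named gene or list past the threshold turned its sign in any setting run. Of the 62 named genes past the threshold, all passed in 7 of the other settings, and 49, 58 and 41 passed with the mean over probes and in the Cy5 and Cy3 orientations. Those 7 include Aquantile scaling, which cannot differ, and the authors' values in 2 forms that are equal. In the settings with 0 calls, 0 of the 62 passed. Print-tip loess, spot flags and slide or scan blocks were not run, since the array has 1 block and the files hold no flags or slide or scan names. Signal over background limits Th, Gch1 and other dim genes.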

Other observations

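The tests of the shared null pool and of the sex-linked genes, the 4 lists in the next paragraph and the genes named there were chosen after the values were seen, and so were the comparison of the 2 general lists between pools and the correlation with genomic span. The span explanation was first judged by that correlation alone, which went with it; the lists matched on span were added after that value was seen and before their own.

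Core histone genes were a further group with rises in the null pool. This list holds H2ac23 and H2ac10, already among the largest rises, so its count and p-values in part repeat them. Of 28 measured, 8 rose and 0 fell, with a median of 0.14 (camera p = 2.12e-09, and p = 0.0981 with an estimated correlation). They included H2ac1 at 0.97 ± 0.21, H2ac20 at 0.50 ± 0.044 and H4c8 at 0.43 ± 0.041. Splicing factor, heterogeneous nuclear ribonucleoprotein and other RNA-binding protein genes, taken by symbol start, gave 2 rises and 5 falls among 102 (camera p = 0.00792, and p = 0.225 with an estimated correlation), among them Hnrnpm at -0.72 ± 0.20. Genes with proteasome subunit symbols, a list that also holds Psmc3ip, which is no subunit, gave 5 rises and 1 fall among 39 (p = 0.0239, and p = 0.238 with an estimated correlation). Hypothalamic neuron genes gave 1 rise among 20, that of Pmch, the precursor of melanin-concentrating hormone, at 0.94 ± 0.30 (p = 0.0956, and p = 0.211 with an estimated correlation). Probes without a gene symbol, which no comparison used, gave 128 rises and 39 falls among 6988 when tested alone.

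Some list genes ranged widely over the heterozygous pools, and 3 of the widest, outside the naming rule, are given. Isl1, a transcription factor of motor and other neurons, read 0.70, 0.84 and -0.71 in the 3 pools, with both arrays of each pool on the same side. Sncb read -0.26, 0.07 and -1.20, and Tcf7l2 read -0.62, 0.46 and -0.21. Rpl13a, also outside the rule, followed the dyes: it read 0.74 to 1.53 with the null RNA in Cy5 and -2.04 to -0.55 with it in Cy3.

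The first pattern weighed is the number of genes past the threshold. One shared null pool enters every ratio, so any peculiarity of that pool counts as a shared change. When 20 data sets were simulated with no effect and 1 shared pool, with each gene's SD taken from the fit, the median count was 325.5 (153 to 500). That simulated pool gave a covariance of 0.0072 between ratios, less than real pools do, so the gap to 908 decides nothing. With a heterozygous pool as the shared reference against the other 2, 726, 847 and 1442 genes had an unadjusted p under 0.01. The null pool gave 1246, 1258 and 1343. Noise of the arrays of a heterozygous reference enters both of its ratios and tends to raise its count, so these counts are on unlike terms. Chance differences of 1 pool may account for many of the calls, and no test here separates the genotype from them.

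The pools' ratios to the null pool correlated across genes at 0.62 (pools 2 and 3), 0.60 (1 and 3) and 0.62 (1 and 2), with covariances of 0.0160, 0.0180 and 0.0190. A shared reference gives such correlations with no effect: with heterozygous pool 1, 2 or 3 as the reference for the same pairs they were 0.61, 0.43 and 0.45, with covariances of 0.0152, 0.00941 and 0.00997. The variance of the null pool among genes above background was 0.0263, against 0.0239, 0.0124 and 0.0121 for the heterozygous pools. The values of a heterozygous pool also hold the noise of its own arrays, which those of the null pool do not, so they are on unlike terms. That noise tends to raise the values of the heterozygous pools. The null pool cannot be split, and its values lie a little above those of heterozygous pool 1 and further above those of pools 2 and 3. This leaves open whether there is an effect beyond a shared pool.

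The second pattern is the higher reading of ribosomal protein and oxidative phosphorylation genes, with a joint median of 0.33 over 151 genes. Other genes of like brightness did not give such a value: of 10000 random lists matched on intensity, the highest median was 0.023. Loess sets the typical ratio near 0 at each intensity, so this outcome was largely fixed by the processing and decides little about brightness. Short genes did read higher than long ones outside these lists (Spearman's rho across genes with genomic span of -0.25 for the mean, -0.22, -0.22 and -0.15 for the null pool over pools 1, 2 and 3, and -0.097 to -0.027 between heterozygous pools), but 10000 lists matched on span and intensity reached at most 0.063, so span alone does not account for the size of the rise. Genomic span is not transcript length, and RNA quality was not tested. Between heterozygous pools the joint median was at most 0.11 in size, against 0.29 to 0.42 for the null pool over each; with 1 null pool, genotype and the handling of that pool cannot be told apart.

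The third pattern is in Xist and Eif2s3y, 2 of the 4 sex-linked genes measured. The other members of that list were not weighed. Xist read -0.84, 0.22 and -0.36, and Eif2s3y read 0.56, -0.47 and 0.46 in the 3 pools. Eif2s3y was well above background on 6 arrays in the null RNA and on 2 of 6 in the heterozygous RNA, so the sizes of its ratios are uncertain. The signs were opposite in 3 of 3 pools, as different shares of female and male embryos in the pools would give. These signs are the pattern itself, so they are no separate test of it. No biological explanation was tested.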
